A study of Mus musculus with 22 samples.

How the data were processed

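RNA 5' ends were counted in primary motor cortex (M1) of male C57BL/6 mice aged 16 to 20 weeks. The mice were either wild type (WT) or BERKO, the name given to mice lacking estrogen receptor beta, the product of Esr2. Per the labels' protocols, a left and a right biopsy of each mouse were taken by needle puncture, and 10 ng of total RNA per biopsy entered STRT sequencing, a method that tags the 5' end of each transcript at reverse transcription. Each biopsy carried its own well barcode, ERCC spike-in RNA was added, and the cDNAs were pooled, amplified by PCR and sequenced in 3 Illumina lanes. The series holds 6 WT and 5 BERKO mice, 22 biopsies in all. Per the labels, 6 BERKO mice entered the experiment and the submitters removed 1 BERKO sample as an outlier; BERKO replicate 1 was not analysed here.

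The authors deposited whole-number read counts per feature, a second table of ratios and an annotation of the features. Per the submitters' processing notes, the work used genome build mm9, Bowtie and TopHat2 2.0.12. How reads were filtered and how features were drawn is not given in the sources used here. Each feature of the deposited count table is a region of 5' ends with a position, a strand and a class such as 5' UTR, upstream, CDS or 3' UTR. The deposited ratio of each feature is its read count divided by the total of the spike-in reads of that library, as recomputed from the 2 tables with a largest difference of 0.0000 reads. The table holds 112460 features, of which 38 are spike-ins, 19 more lie on spike-in sequences and 37 lie on a ribosomal RNA repeat reference; all of these were left out of the tests. The counts are reads after PCR, not molecules, so intervals and floors cover counting error only.

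All 64 columns of the count table were matched to biopsies by side, genotype and mouse number in their names, with the lane as a repeat run. The last digit of a column name was read as the mouse number, which the labels give for each biopsy but do not tie to that digit in words. The right and left biopsies matched in this way correlated by -0.15 to 0.452 in their deviations from the group means, and 4 of 11 right biopsies correlated best with the left biopsy of their own mouse, so the values do not settle this reading. The sums per mouse and the mouse block rest on it. Lanes of a biopsy were summed, since lane 1 and lane 3 of 21 biopsies differed by a chi-square per gene of 0.69 to 0.849, which is within sampling noise. Different biopsies of a group differed by at least 4.32 per gene. The left biopsy of BERKO replicate 5 has 1 lane and the others have 3. Features with a single gene symbol, 95410 in number, were summed to 15297 genes. Features with several symbols or none held 5.22% of the endogenous reads, including those on the ribosomal RNA repeat reference. Apart from these ribosomal features, they entered the feature-level test only.

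The mouse was the replicate. Counts of both sides were summed per mouse for the genotype comparison, at gene level and at the level of the deposited features. Each side was also tested alone, left was compared with right with the mouse as a block, and the difference of the genotype effect between the sides was tested in the same model. All of these used edgeR 4.0.16 (quasi-likelihood test with robust dispersion, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, with TMM scaling on endogenous genes and the default expression filter. Standard errors are the log2 fold change divided by the square root of F. TMM factors ranged from 0.948 to 1.09, and the common biological coefficient of variation was 36.7%. Levels are given as CPM of gene reads after TMM, as mean ± SD over mice. Gene lists, 28 in all, were tested with camera in limma 3.58.1 with a preset correlation of 0.01 where 5 or more members were measured, which held for 25 lists. Read shares were compared with two-sided exact permutation tests over all 462 splits of the 11 mice, whose smallest possible p is 0.00216, and genes near Esr2 with Fisher's exact test in a window of 10 Mb. The 9 read shares and totals compared this way form a family, with Benjamini-Hochberg values given beside the raw p.

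Groups, tests, gene lists and most alternatives were fixed before the data were examined. The named genes followed a rule fixed at the same time: of genes past the threshold with a mean of 20 or more counts per mouse in the higher genotype and the same sign on both sides, up to 10 in each direction, and then the genes next in order of p until 20 were named; up to 4 members of each list by p; the 5 smallest p for left against right when none passed; and the 3 smallest p for each side and for the interaction. The 15 features past the threshold, and all 5 genes past it on the right side, are named as well. Some list members that the rule takes are not reported here. The features other than those of the named genes were chosen after their values were seen.

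The tests were tested on simulated data, with counts drawn from the real means, dispersions and library sizes and a known set of genes changed by 1 or 2 log2 units. For the genotype comparison per mouse, run on 8670 genes, 40.2% of genes changed by 1 log2 unit and 80.9% of those changed by 2 were recovered. The recovered shares at 1 and 2 log2 units were 22.2% and 70.1% for features (12026 features), 31.2% and 81.1% for the right side (7300 genes), and 32.3% and 83.1% for the left side (6200 genes). They were 48.9% and 97.5% for left against right (6405 genes) and 1.1% and 41.7% for the interaction (7909 genes). For these 2 tests the libraries of a mouse were drawn without a shared mouse effect. Their recovered shares can therefore differ from those in the paired data. Between 2.3% and 6.8% of simulated calls were false. In simulated lists, drawn with no correlation between genes, the list shifted by 0.5 was called and 0 of the others were. The real lists had estimated correlations of up to 0.715 (myelin). The simulation therefore does not show how often the preset correlation gives false calls in them.

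Alternatives were RLE size factors, spike-in scaling, no filter, a filter at a mean of 20 counts, DESeq2 1.42.0, limma-voom, mouse as a random effect, the deposited ratios on a log2(ratio + 1) scale, promoter features alone (5' UTR and upstream), a threshold of 0.1, the replicate number as a block, and leaving out each mouse in turn. For lists, an estimated correlation and fry were added. Further alternatives were chosen after seeing the data: leaving out 3 WT libraries that stood apart on a principal component, lane 3 alone, and thinning to 968219 gene reads per mouse. The tests of the mitochondrial and gene body read shares were also chosen after seeing the data. For each comparison 60 splits of the samples were drawn, the real one among them. Stretches of at least 50 bases at 95% identity or more between named genes and other genes were sought with BLAST 2.17.0 in GENCODE mouse transcripts, for names only, since that annotation is on another genome build and no coordinate of it was used. That search cannot tell a second copy from overlapping annotations of the same locus, nor whether a stretch covers the counted 5' ends. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.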

Results

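The data comprised read counts of 22 M1 cortex biopsies, with a left and a right biopsy from each of 6 WT and 5 BERKO mice. Total reads per biopsy ranged from 249751 in the left biopsy of BERKO replicate 5 to 2018833 in the right biopsy of WT replicate 1. Per mouse, WT had 2205000 ± 570100 reads (SD, n = 6) and BERKO 1406000 ± 250400 (SD, n = 5), a difference with an exact permutation p of 0.0152 (adjusted 0.0342). Plate rows were read from the first letter of a code in the column names, taken here as the well. By this reading, WT biopsies occupied plate rows A to C and BERKO biopsies D to F. Within these the right biopsies were in rows A and D and the left biopsies in the others. Plate row therefore cannot be told apart from genotype or from side. On the first principal component of 5731 genes, which held 14.8% of the variance, 3 WT libraries stood apart from the other 19: the right biopsy of WT replicate 1 at -41.61, its left biopsy at -53.32 and the left biopsy of WT replicate 2 at -49.22.

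Esr2, the gene BERKO mice lack, was close to undetected in both genotypes. Its features lie on the minus strand of chromosome 12 (mm9) at 77246443 (CDS), 77278038 (5' UTR) and 77278248 (upstream). The right biopsy of WT replicate 1 had 3 reads, all upstream, and the left biopsies of BERKO replicates 3 and 5 had 6 and 4 reads, all in the CDS feature. The other 19 biopsies had 0 reads, which allows up to 1.96 CPM in the deepest of them and 6.42 in the shallowest, before TMM scaling. The genotype labels could therefore not be checked from Esr2 at this depth. How far the deleted part overlaps these features is not given in the sources used here.

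The comparison of BERKO with WT asked which transcripts differ in motor cortex when estrogen receptor beta is missing. In BERKO mice, 4 genes rose and 3 fell. Cdkn1a, a cyclin-dependent kinase inhibitor, rose from 41.9 ± 16.3 to 107.5 ± 29.5 CPM (SD, n = 6 and 5), by 1.37 ± 0.26 log2 units (SE). Cdk5r1, the neuronal activator of the kinase Cdk5, rose from 31.9 ± 13.99 to 81.1 ± 19.5 CPM, by 1.35 ± 0.27. Lingo1, a membrane protein that restrains myelination and axon growth, rose by 0.99 ± 0.19, and Arpc2, a subunit of the actin-nucleating Arp complex, by 0.85 ± 0.16. Uqcrb, a subunit of respiratory complex III, fell from 163.2 ± 25.97 to 67.1 ± 23 CPM, with a log2 change of -1.29 ± 0.21. Rpl22l1, a ribosomal protein paralog, fell from 25.5 ± 8.22 to 1.64 ± 1.63 CPM, with a log2 change of -3.80 ± 0.59, and Gm15421, annotated as noncoding, fell with a change of -1.99 ± 0.40.

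The adjusted p of edgeR's quasi-likelihood test was 0.00554 for Rpl22l1, 0.00573 for Uqcrb, 0.0278 for Cdkn1a and Arpc2, 0.0433 for Lingo1 and 0.0484 for Cdk5r1 and Gm15421. All 5 BERKO mice lay above or below every WT mouse for 6 of these genes, and 4 of 5 for Cdkn1a. The reads of Cdkn1a came mainly (72%) from a 5' UTR feature at 29230719 on chromosome 17, those of Uqcrb (99.4%) from a 5' UTR feature at 67006262 on chromosome 13, and those of Rpl22l1 (93.4%) from a 5' UTR feature at 28704433 on chromosome 3. The leading feature of Arpc2 (49.8%) was upstream, at 74283107 on chromosome 1. The reads of Cdk5r1 (97.4%) came from a 3' UTR feature at 80293456 on chromosome 11 and those of Lingo1 (71.7%) from a CDS feature at 56467884 on chromosome 9, classes whose share of reads was higher in BERKO as a whole. Rpl22l1 and Gm15421 share 395 bases at 99.494% identity, so their reads may not be separable and the 2 calls are uncertain as separate calls. Uqcrb shares 336 bases at 98.214% with Gm2962, and Arpc2 shares 510 bases at 96.078% with AC154544.1, so these are uncertain in the same way. Shorter stretches were found for Cdkn1a in 67 other genes (longest 165 bases at 95.152%, Ctcfl). For Lingo1 they were found in 9 (longest 81 bases at 96.296%, Gm37932), so both carry this uncertainty too.

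Of 9025 genes tested, 7 passed the threshold, and 895 had an unadjusted p under 0.05 (476 higher, 419 lower) where 451 were expected by chance. In 120 genes (1.33%) the genotypes did not overlap, against 0.433% by chance. The count rested on single mice: it was 18 without WT replicate 4, 4 without WT replicate 2, 3 without WT replicates 3 or 5 or BERKO replicate 6, 2 without WT replicate 6 or BERKO replicates 4 or 5, and 1 without BERKO replicate 3. Without a mouse, Rpl22l1 passed in each of the 11 fits and Uqcrb in all but that without BERKO replicate 3 (adjusted p = 0.0595). Cdkn1a and Arpc2 did not pass without WT replicates 3, 5 or 6 or BERKO replicates 3, 4 or 5 (0.0538 to 0.132), nor Cdkn1a without BERKO replicate 6 (0.0832). Lingo1 did not pass without WT replicates 2, 3 or 6 or BERKO replicates 3, 4, 5 or 6 (0.069 to 0.167), and Cdk5r1 without these or WT replicate 5 (0.0832 to 0.228). Gm15421 passed only without WT replicate 4, with 0.0538 to 0.165 in the other 10 fits. With promoter features alone, Lingo1 (0.94 ± 0.30, adjusted p = 0.342), Arpc2 (0.68 ± 0.19, 0.229) and Gm15421 (-1.90 ± 0.39, 0.0543) did not pass; the change of Lingo1 was close to that with all features and its SE larger. In limma-voom, Cdk5r1 (0.055), Lingo1 (0.0661), Arpc2 (0.0598), Rpl22l1 (0.134) and Gm15421 (0.247) did not pass, and after thinning to 968219 gene reads per mouse Cdk5r1 (1.31 ± 0.28), Lingo1 (0.98 ± 0.21) and Gm15421 (-1.998 ± 0.42) did not (0.0672 each), with changes close to those reported. Without the 3 WT libraries that stood apart, Cdkn1a (1.14 ± 0.26, adjusted p = 0.08), Cdk5r1 (1.17 ± 0.25, 0.0537) and Gm15421 (-1.70 ± 0.465, 0.228) did not pass. Their changes were smaller than reported but in the same direction. Cdk5r1 and Gm15421 also missed the threshold with the stricter filter (0.0505 each) and with mouse as a random effect (0.114 and 0.156), and Gm15421 with spike-in scaling (0.0562) and on the log2(ratio + 1) scale (0.0783). Spike-in scaling, which moved the median gene by 0.19 log2 units, gave 43 higher and 2 lower genes. The log2(ratio + 1) scale gave 95 higher and 2 lower. DESeq2 gave 33 higher and 12 lower, but it gave an adjusted p to 2724 genes, against 9025 in edgeR. Its calls held 4 of the 7 genes called in edgeR.

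**Figure D1:**
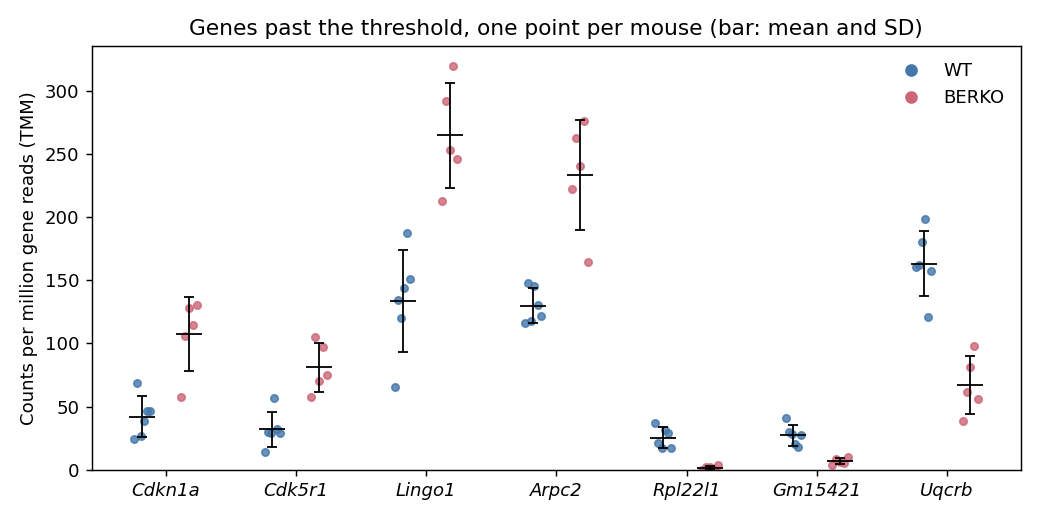
CPM of gene reads (TMM-scaled, vertical axis) of the 7 genes past the threshold, with a point per mouse (6 WT, 5 BERKO) and bars for the mean and SD. Rpl22l1 averaged 25.5 in WT and 1.64 in BERKO, while Cdkn1a averaged 41.9 and 107.5.

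The next 13 genes in order of p did not pass the threshold. Higher in BERKO, by values that did not pass, were Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons (0.76 ± 0.18), Ppp3ca, the catalytic subunit of calcineurin (0.75 ± 0.17), Kcnh1, a voltage-gated potassium channel (1.04 ± 0.23), Mark2, a microtubule-regulating kinase (0.78 ± 0.19), Dynll2, a dynein light chain (0.78 ± 0.19), and Aqp4, the water channel of astrocyte endfeet (0.89 ± 0.22). Cbx6, a Polycomb protein (0.65 ± 0.15), Atxn7l3b (0.69 ± 0.15) and the small GTPase genes Rabl6 (0.97 ± 0.21) and Rasl10b (1.32 ± 0.30) were also higher. Lower were Snapc1, a subunit of the complex that activates small nuclear RNA genes (-1.17 ± 0.26), Dhrs7, a dehydrogenase (-1.01 ± 0.24), and Actr8, a subunit of a chromatin remodelling complex (-0.74 ± 0.18). Adjusted p ranged from 0.0778 to 0.164 in edgeR. A stretch of 563 bases of Cbx6 is identical in Npcd and 298 bases of Snapc1 in Gm49321. Whether these are second copies or overlapping annotations of the same locus was not tested, so both are uncertain. So are Actr8 (longest stretch 109 bases at 95.413%, Kctd20), Rabl6 (144 bases at 95.139%, Gm28424) and Dhrs7 (81 bases at 97.531%, Gm44428). Atxn7l3b, Rabl6, Kcnh1, Snapc1, Cbx6 and Ppp3ca passed without WT replicate 4 (adjusted p 0.0248 to 0.0369), Atxn7l3b without BERKO replicate 2 (0.0317) and Dhrs7 without WT replicate 1 (0.00356). Dhrs7 also passed without the 3 WT libraries that stood apart (0.00201). DESeq2 called Atxn7l3b, Rabl6, Cbx6, Ppp3ca, Slc17a7, Dhrs7, Dynll2, Actr8 and Mark2 (0.00589 to 0.0174). Spike-in scaling called Kcnh1 and Rasl10b among others (0.0384 and 0.0392). Atxn7l3b passed most often, in 6 of 23 alternatives, and Actr8 least, in 1 of 23.

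Markers of glia and vessels leaned higher in BERKO as lists. Astrocyte genes had a median log2 change of 0.25 (25 measured, 22 positive), microglial genes 0.32 (22 measured, 19 positive), endothelial genes 0.41 (14 measured, 13 positive), pericyte and smooth muscle genes 0.27 (12 measured, 10 positive), meningeal fibroblast genes 0.57 (15 measured, 13 positive) and myelin genes 0.23 (29 measured, 22 positive). No member of these lists passed over all genes tested. Adjusted over the list alone, 3 astrocyte genes passed, namely Aqp4, Clu (0.44 ± 0.13), an abundant secreted chaperone, and Mlc1 (0.50 ± 0.16), an astrocyte membrane protein. So did 3 microglial genes, Ctss (0.53 ± 0.15), a lysosomal protease, Cx3cr1 (0.62 ± 0.21), the fractalkine receptor, and C1qa (0.62 ± 0.21), a complement subunit, as well as endothelial Cldn5 (0.70 ± 0.19), a tight junction protein, and pericyte Rgs5 (0.60 ± 0.18). In the myelin list 0 genes passed, and Mbp, myelin basic protein, was at 4036 ± 1694 CPM in WT and 5315 ± 2010 in BERKO.

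With the preset correlation, camera gave these lists adjusted p of 4.76e-07 (astrocyte), 5.34e-05 (microglia), 0.000138 (endothelial), 0.00317 (pericyte), 0.000956 (meningeal) and 0.00443 (myelin). With an estimated correlation, none of these lists passed in camera: the adjusted p was 0.414 for astrocyte, microglial and pericyte genes, 0.417 for endothelial, 0.446 for meningeal and 0.724 for myelin genes. Without the 3 WT libraries that stood apart, the myelin list changed direction (adjusted p = 0.516) and the meningeal list lost its call (0.0914). Without WT replicate 1 alone the same happened to both (0.954 and 0.0944), and the myelin list was not called without BERKO replicate 2 (0.228). The pericyte list was not called on the left side alone (0.154) nor the meningeal list on the right side alone (0.19). Reads in CDS and 3' UTR features were higher in BERKO alongside these lists, at 17.6% against 13.9% of endogenous reads.

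Some neuronal lists leaned the same way. The interneuron (-0.09), GABA (-0.05) and striatal (-0.37) lists, which were not called, had negative medians. Axon and cytoskeleton genes had a median of 0.23 (24 measured, 20 positive, adjusted p = 0.000241 by camera), immediate early genes 0.41 (19 measured, 13 positive, 0.0124), ion channel genes 0.12 (39 measured, 22 positive, 0.016) and synaptic vesicle genes 0.13 (27 measured, 17 positive, 0.0267). With an estimated correlation the adjusted p was 0.414 for the first pair and 0.446 for the second pair. No member passed over all genes tested. Adjusted over the list alone, Kcnh1, a potassium channel, passed as higher, as did Vamp2 (0.48 ± 0.13), the vesicle fusion protein, while Rab3c (-0.53 ± 0.16), a vesicle GTPase, passed as lower. Egr1, an activity-induced transcription factor, was at 55.8 ± 28.3 CPM in WT and 119.3 ± 48.9 in BERKO (1.12 ± 0.43), and Map1a, a microtubule protein, differed by 0.56 ± 0.23, neither passing. With promoter features alone the axon list (adjusted p = 0.0829) and the vesicle list (0.594) lost their calls and the ion channel list changed direction (0.594), and without the 3 WT libraries that stood apart the ion channel (0.163) and vesicle (0.0914) lists lost theirs. The immediate early list was not called without WT replicate 3 (0.071), the ion channel list without WT replicate 1 or BERKO replicates 3 or 5 (0.0557 to 0.132), and the vesicle list without WT replicates 1, 2 or 6 or BERKO replicates 3 or 5 (0.0617 to 0.204) or on the left side alone (0.362).

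Cytosolic ribosomal protein genes had a median of 0.08 (77 measured, 56 positive, camera adjusted p = 0.000782, adjusted p = 0.607 with an estimated correlation), with 0 members past the threshold by either adjustment. On the left side alone this list pointed down (adjusted p = 0.344), and it was not called without WT replicate 3 (0.0832). Genes of oxidative phosphorylation encoded in the nucleus had a median of -0.02 (77 measured, 43 negative, camera adjusted p = 0.341). Uqcrb was the member past the threshold over all genes and over the list alone, and Cox7b (-0.38 ± 0.13) and Ndufa6 (-0.38 ± 0.13), subunits of complexes IV and I, did not pass. Camera called this list lower on the left side alone (adjusted p = 0.00114), without the 3 WT libraries that stood apart (0.0173) and without BERKO replicate 6 (0.0403). It pointed up, without a call, on the right side alone (0.875), with promoter features alone (0.118) and without BERKO replicate 4 (0.942). The fry test for change in either direction called it (adjusted p = 0.0398).

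The other 13 lists were not called by camera. Adjusted p was 0.102 for the glutamatergic synapse list, where Slc17a7 and Camk2a (0.55 ± 0.14), the main postsynaptic kinase, passed over the list alone, and 0.753 for the GABA list, where Gad1 (-0.54 ± 0.16), which makes GABA, and Nlgn2 (0.75 ± 0.22), an inhibitory synapse adhesion protein, did so in opposite directions. It was 0.62 for interneuron genes, with Cck (0.62 ± 0.15) past the list alone, and 0.753 for oligodendrocyte precursor genes, with Sox10 (-1.79 ± 0.48). It was 0.206 for upper and 0.753 for deep cortical layer genes, 0.936 for striatal genes, 0.2 for circadian genes, 0.202 for chaperones, 0.294 for steroid and nuclear receptors, 0.341 for glycolysis, 0.434 for cholesterol synthesis and 0.62 for interferon genes. Choroid plexus (3 measured), blood (2 measured) and mitochondrially encoded genes (0 measured under gene symbols) were too few to test. For the steroid receptor, interneuron, GABA, oligodendrocyte precursor, deep layer and striatal lists the camera direction was up while the median or the mean was negative. The glutamatergic list was called without WT replicate 3 or BERKO replicates 2 or 6 (0.0223 to 0.0444), the interneuron list on the right side alone (0.0191) and after thinning (0.0244), cholesterol synthesis as lower on the left side alone (0.0319, against 0.875 and upward on the right), the chaperones without WT replicate 2 (0.0326) and the circadian genes without BERKO replicate 6 (0.0234). In all, 11 of 25 lists were called with the preset correlation, and 7 without WT replicate 1. With an estimated correlation 0 lists were called (adjusted p of 0.414 to 0.724 for the 11 lists), and 0 by fry for a common direction.

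Mitochondrial reads as a whole took a lower share in BERKO. They took 1.70% ± 0.248 of endogenous reads in WT (SD, n = 6) and 0.836% ± 0.0958 in BERKO (SD, n = 5), a log2 difference of -1.01 with an exact permutation p of 0.00216, the smallest possible (adjusted 0.00972). The genotypes did not overlap, at 1.37% to 1.97% in WT and 0.691% to 0.915% in BERKO, and the log2 difference was -1.03 on the right and -0.98 on the left. At feature level, the 5' end at 1094 of the mitochondrial chromosome fell with a log2 change of -1.19 ± 0.11 (edgeR adjusted p = 2.49e-06), that at 11142 with -2.50 ± 0.27 (7.85e-05), that at 9459 with -0.92 ± 0.13 (0.00141), that at 14145 with -0.72 ± 0.13 (0.0217) and that at 6190 with -1.16 ± 0.22 (0.0306). Of the features with 1000 or more counts, those at 16188 (minus strand, -0.35 ± 0.16, edgeR adjusted p = 0.41) and 5406 (0.21 ± 0.14, 0.578) did not pass. The feature at 1094 held 207275 reads over all samples and the next largest, at 14145, held 44421. The share therefore mainly reflects the 5' end at 1094.

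Outside the mitochondrial chromosome, 10 features passed. A region without gene annotation on chromosome X (minus strand, 103382246) had 0 reads in the 6 WT mice and 116 reads in BERKO, spread over all 5 mice, and was at least 72.8-fold higher against a floor of 3 counts over the WT group. Another without annotation on chromosome 6 (plus strand, 79768098) fell with -2.71 ± 0.41, from 727 reads in WT to 59 in BERKO. The Rpl22l1, Uqcrb, Gm15421 and Cdk5r1 features passed in the direction of their genes. A 5' UTR feature of Maged1 on chromosome X (91787363) fell (-0.88 ± 0.15), as did that of Actr8 on chromosome 14 (30791591, -0.84 ± 0.17), while a CDS feature of Rnf214 on chromosome 9 (45708206, 1.87 ± 0.34) and a 3' UTR feature of Cx3cl1, which encodes fractalkine, on chromosome 8 (97305336, 0.99 ± 0.19) rose. As whole genes, Maged1, Rnf214 and Cx3cl1 did not pass (adjusted p of 0.381, 0.429 and 0.388).

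In all, 15 of 13128 features passed, 4 higher and 11 lower, with adjusted p up to 0.0494. The count was 47 without WT replicate 4, 9 without WT replicate 2 or BERKO replicate 3, and 8 without WT replicate 3 or BERKO replicates 4, 5 or 6. Both unannotated regions, the Rpl22l1 feature and those at 1094 and 11142 of the mitochondrial chromosome passed in each of their alternatives. Spike-in scaling gave 36 higher and 4 lower, and DESeq2 68 higher and 61 lower, with an adjusted p for 7778 features. With spike-in scaling the features at 9459 (0.0791), 14145 (0.22) and 6190 (0.0953) of the mitochondrial chromosome and those of Uqcrb (0.0553), Maged1 (0.162), Gm15421 (0.0725) and Actr8 (0.255) did not pass, nor that of Actr8 with RLE size factors (0.0545). Without the 3 WT libraries that stood apart, the Maged1 (0.108), Gm15421 (0.195), Cdk5r1 (0.0603) and Cx3cl1 (0.05) features did not pass. Over all alternatives their changes kept their direction, at -0.968 to -0.637, -2.258 to -1.732, 1.179 to 1.623 and 0.788 to 1.274 in that order. Of the 11 fits without a mouse, the Cx3cl1 (0.0512 to 0.138), Actr8 (0.0663 to 0.155) and Gm15421 (0.0542 to 0.122) features did not pass in 9, Cdk5r1 in 8 (0.0878 to 0.187), 14145 in 7 (0.0574 to 0.114), Rnf214 (0.0516 to 0.112) and 6190 (0.0679 to 0.145) in 6, and Maged1 in 2 (0.0604 and 0.0758).

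**Figure D2:**
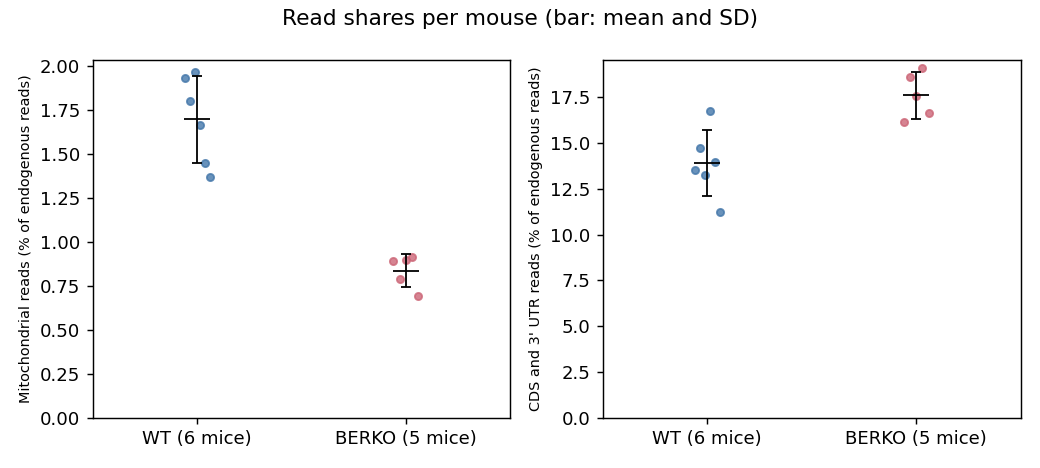
Share of endogenous reads (%, vertical axes) on mitochondrial features (left panel) and on CDS and 3' UTR features (right panel), with a point per mouse (6 WT, 5 BERKO) and bars for the mean and SD. The mitochondrial share averaged 1.70% in WT and 0.836% in BERKO, and the CDS and 3' UTR share 13.9% and 17.6%.

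Reads inside genes were more frequent in BERKO. CDS and 3' UTR features together took 13.9% ± 1.80 of endogenous reads in WT (SD, n = 6) and 17.6% ± 1.27 in BERKO (SD, n = 5), a log2 difference of 0.35 with an exact permutation p of 0.00866 (adjusted 0.026). The difference was 0.42 on the right (exact permutation p = 0.00433) and 0.26 on the left, where it did not pass (exact permutation p = 0.108). The median feature was higher by 0.39 in 3' UTRs (1699 features) and by 0.38 in CDS (2996), and at -0.16 in 5' UTRs (5629) and -0.18 upstream of genes (1443). Of the 476 genes higher at an unadjusted p under 0.05, 227 (47.7%) were read mainly in CDS or 3' UTR features, against 25 of the 419 lower genes (5.97%) and 1701 of all 9025 (18.8%). Lingo1, Cdk5r1, Kcnh1, Slc17a7, Dynll2, Mark2, Cbx6, Rasl10b, Rabl6 and Ppp3ca had their leading feature in a CDS or 3' UTR, and 2 of them had a value with promoter features alone, Lingo1 at 0.94 ± 0.30 (0.99 ± 0.19 with all features) and Ppp3ca at 0.21 ± 0.29 (0.75 ± 0.17).

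**Figure D3:**
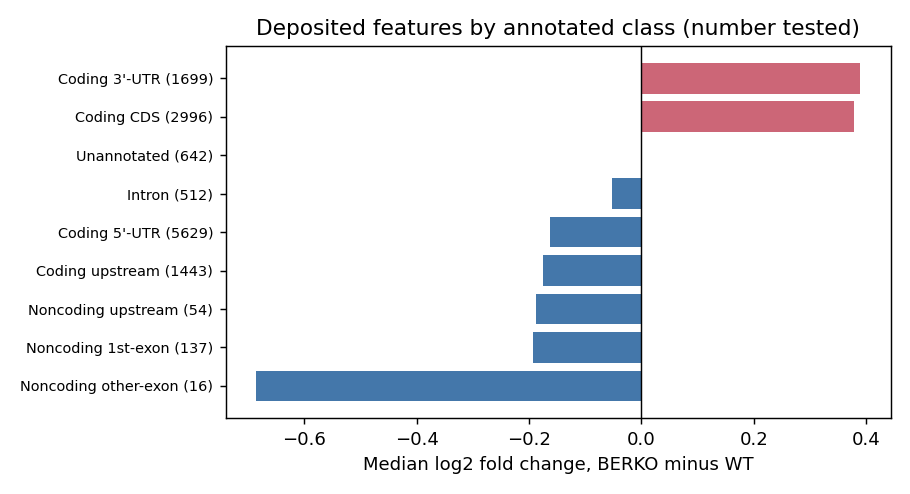
Median log2 fold change (BERKO minus WT, horizontal axis) of tested features by annotated class, with the number of features in brackets. CDS and 3' UTR features had medians of 0.38 and 0.39, and 5' UTR features -0.16.

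The spike-in RNA gave a library-level readout of endogenous RNA. WT mice had 541 ± 90.6 endogenous reads per spike-in read (SD, n = 6) and BERKO mice 641 ± 74.1 (SD, n = 5), 1.19-fold, a log2 difference of 0.26 that did not pass (exact permutation p = 0.0823, adjusted 0.123). It passed without WT replicate 1 (0.31, exact permutation p = 0.0397) and without WT replicate 5 (0.30, exact permutation p = 0.0476). Spike-in reads themselves were fewer in BERKO (2182 ± 244.5 against 4038 ± 660.0, exact permutation p = 0.00216, the smallest possible).

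Genes near Esr2 were examined because a knockout can carry flanking donor DNA. Within 10 Mb, 0 of 96 genes passed in edgeR against 7 of 8929 elsewhere (Fisher's exact p = 1). With so few calls this test could hardly show an excess near Esr2, so it decides nothing. Of the 96 genes, 13 (13.5%) had an unadjusted p under 0.05 against 9.88% elsewhere (Fisher's exact p = 0.229). Snapc1 (75065500) and Dhrs7 (73765789) lie in this window, as do Mdga2 (68322204, -1.86 ± 0.49), Fntb (77938415, -2.33 ± 0.62) and Dbpht2 (75399462, 1.93 ± 0.52), and none passed, with adjusted p of 0.0778 to 0.179. These 5 of 96 genes had an unadjusted p under 0.001, against 41 of 8929 elsewhere (0.459%, Fisher's exact p = 0.000119). That threshold and Mdga2, Fntb and Dbpht2 were chosen after the values were seen, and neighbouring genes are not independent.

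On the right side alone, 4 genes fell and 1 rose in BERKO. Nr3c2, the mineralocorticoid receptor, fell from 21.3 ± 14.8 to 0.235 ± 0.525 CPM (SD, n = 6 and 5), from 179 reads in WT to 1 in BERKO. Dcaf17, a ubiquitin ligase adaptor, fell from 34.4 ± 17.5 to 3.70 ± 2.74 CPM (-3.22 ± 0.59), with 289 reads against 14. Dcaf17 shares stretches with 22 other genes (longest 190 bases at 95.263%, Ftx), so it is uncertain. In the sums per mouse neither passed (Nr3c2 -2.79 ± 0.86, adjusted p = 0.291; Dcaf17 -1.58 ± 0.40, 0.179), and on the left Dcaf17 differed by -0.45 ± 0.58 (adjusted p = 0.918) while Nr3c2 did not pass the expression filter. Uqcrb (-1.48 ± 0.27) and Rpl22l1 (-3.39 ± 0.64) fell and Cdk5r1 rose (1.67 ± 0.31), as in the sums per mouse. Adjusted p in edgeR was 0.02 for the first 2, for Uqcrb and for Cdk5r1, and 0.023 for Rpl22l1. Of 7696 genes tested 5 passed, and 635 had an unadjusted p under 0.05. The count was 0 without WT replicates 2, 3 or 5 or BERKO replicates 2, 3 or 4, 1 without WT replicate 6 and 3 without BERKO replicate 5. Rpl22l1 did not pass without WT replicate 4 (adjusted p = 0.0769), nor Dcaf17 without BERKO replicate 6 (0.0594). DESeq2 gave 10 higher and 13 lower, and spike-in scaling 2 higher and 1 lower, with which Uqcrb (0.194), Dcaf17 (0.0534) and Rpl22l1 (0.0691) did not pass.

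On the left side alone, 0 of 6616 genes passed in edgeR, with 447 at an unadjusted p under 0.05 and 5 genes by DESeq2. The smallest p belonged to Lingo1 (1.13 ± 0.23, adjusted p = 0.202), Cd200, an immune-inhibitory membrane protein (-1.32 ± 0.30, 0.336), and Aqp4 (1.14 ± 0.27, 0.336). Lingo1 was at 121.0 ± 30.2 CPM in WT and 264.6 ± 49.2 in BERKO. Without WT replicate 4, 1 gene passed, Lingo1 (adjusted p = 0.0452).

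The left and right cortex of the same mice were compared to ask whether the sides differ, although 0 plate rows held biopsies of both sides. Apoe, the main lipid carrier of astrocytes, was at 5284 ± 1089 CPM on the right and 7079 ± 1903 on the left (SD, n = 11), lower on the right in 10 of 11 mice (-0.43 ± 0.10). H2-K1, a class I histocompatibility gene (-1.03 ± 0.23), and Tubb2b, a beta tubulin (-0.61 ± 0.14), were also lower on the right in 10 of 11 mice. Pde1a, a calmodulin-dependent phosphodiesterase, was higher on the right in 11 of 11 mice (0.64 ± 0.15), and B3galt2, a galactosyltransferase, in 10 of 11 (0.68 ± 0.16). None passed in edgeR, with adjusted p of 0.206 to 0.223. In all, 0 of 6651 genes passed, 402 had an unadjusted p under 0.05, and DESeq2 called 18 of the 2525 genes it gave an adjusted p. Without BERKO replicate 2, 3 genes passed, Apoe and B3galt2 among them (adjusted p = 0.0254). Tubb2b shares 1350 bases at 96.444% with Tubb2a and H2-K1 287 bases at 95.122% with Gm8909, so both are uncertain.

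The genotype effect did not differ detectably between the sides, but the test had little power in simulation. There it recovered 1.1% of genes changed by 1 log2 unit and 41.7% of those changed by 2. The simulated libraries of a mouse shared no mouse effect, so power in the paired data can differ. An absence of calls therefore does not show that the sides agree. Of 8308 genes, 0 passed for the interaction in edgeR, 271 had an unadjusted p under 0.05 where 415 were expected by chance, and DESeq2 called 0. The smallest p belonged to Il1f9, an interleukin-1 family cytokine, Rwdd4a, and Pgrmc1, a membrane progesterone-binding protein, whose genotype difference on the right minus that on the left was 0.95 ± 0.27. All 3 had an adjusted p of 0.998, and Il1f9 is uncertain, since 55 of its bases are identical in Gm19757. For Nr3c2 and Dcaf17, called on the right, the unadjusted interaction p in edgeR was 0.103 and 0.00935.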

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

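The tests of an equal mitochondrial change, of plate position, of the neuronal lists, of the glial and vascular lists over mice, and the later tests of the gene body reads were chosen only after the result was seen.

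Outlying samples appeared in 4 of 110 groups examined, where chance gives 5.5. WT replicate 3 had the highest mean log2 CPM of the glutamatergic synapse list among WT mice, 6.004, with the next at 5.792, and of the GABA list, 6.034, with the next at 5.915. WT replicate 1 had the lowest value of the striatal list, 3.768, with the next at 4.764. Tubb2b differed between right and left by -1.638 in WT replicate 3, with the next WT mouse at -0.718. Outside the main measurement, reads on the ribosomal RNA repeat reference took 0.4607% of reads in BERKO and 0.3251% in WT (exact permutation p = 0.0368, adjusted 0.0662).

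Genes read mainly in CDS and 3' UTR features were higher in BERKO. With total reads as a covariate the log2 difference of the read share was 0.354, beside 0.347 without it (permutation p = 0.00433). The shuffled genotypes did not keep the link between genotype and depth, so this p can be too small. Library depth as the whole cause therefore stays undecided. RNA fragments with 5' ends inside genes stay open as a candidate explanation: within a gene and a mouse, the log2 ratio of gene body to promoter reads was 0.476 higher in BERKO (exact permutation p = 0.00649), in 1482 of 1741 genes. An earlier test met its bound against this, with a median promoter change of 0.384 (bootstrap interval 0.254 to 0.5) beside 0.569 for all features, but it is void, because its genes were chosen on reads of which a median of 19.4% were promoter reads. A test on genes chosen by gene body reads alone gave 0.138 and decides nothing, since its scaling removes the class difference, and genotype itself stays open and untested.

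Mitochondrial reads were lower in BERKO. With total reads as a covariate the log2 difference was -0.923, beside -1.015 without it (permutation p = 0.00433). That p has the same limit as the one for gene body reads, so library depth as the whole cause stays undecided here too. An equal fall of all abundant mitochondrial 5' ends is argued against. Of 7 abundant features, 3 lay over 3 SE from the total and the farthest by 8.59 SE. These features are 5' ends without gene annotation, so whether whole transcripts fell equally stays undecided. Plate position and genotype cannot be told apart, as 0 plate rows hold both genotypes. A genotype effect on mitochondrial RNA was not tested apart from this.

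Glial and vascular lists were called higher in BERKO, among 11 lists called with the preset correlation. With an estimated correlation 0 lists were called, and 0 by fry for a common direction. Chance cannot be excluded: 13 of 60 splits of the mice called as many lists, and the highest other split called 14. More 5' ends inside genes stays open: 8 lists were called with promoter features alone, which met the bound set against it, but that bound was wrong, since the other splits called a median of 8 lists with all features. Over mice, the mean of the 6 glial and vascular lists in promoter reads was 0.421 higher in BERKO (exact permutation p = 0.0649). With all features it was 0.374 higher (exact permutation p = 0.0693). The shift was no smaller without gene body reads, but neither value passed. Of the single lists in promoter reads, astrocyte (0.374, exact permutation p = 0.026) and microglial genes (0.312, exact permutation p = 0.0368) had the smallest p. No list passed after adjustment, with a smallest adjusted p of 0.0942. A lower share of neurons cannot be told apart, because the neuronal lists were 0.126 higher in BERKO without passing (exact permutation p = 0.143). Neither can the 3 WT libraries that stood apart, without which 7 of the 11 lists were called.

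For the counts of genes, chance is argued against but not excluded in 3 comparisons, which rest on the same mice. Of 462 possible splits 60 were used, so 1 of 60 is the smallest share that can be reached. With a mouse left out, the counts fell to as few as 1 in the sums per mouse and 0 on the right. For BERKO against WT per mouse, 1 of 60 splits, the real one, gave as many genes (7, highest other 2), for features 1 of 60 (15, highest other 1) and for the right side 1 of 60 (5, highest other 2). For the left side (0, highest other 1), left against right (0, highest other 2) and the interaction (0, highest other 10), 60 of 60 gave as many by construction, since the real count was 0, so that this comparison decides nothing.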

How the results depend on the processing

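The tests without 3 WT libraries, on lane 3 alone, on thinned counts, on lists with promoter features, of both read shares, and of genes near Esr2 by unadjusted p were chosen only after the result was seen. Across the comparisons 137 alternative values kept their side of the threshold or stayed within 1.5 times, 48 moved by more, 3 lost the threshold and 4 gained it. For named genes and features 742 kept their side, 168 lost the threshold, 68 gained it and 0 changed direction, and for lists these were 410, 44, 13 and 33. For genes per mouse (7 as reported), the count was 14 with no filter, 45 with DESeq2, 45 with spike-in scaling, 2 with limma-voom, 97 on log2(ratio + 1), 4 after thinning, 13 at a threshold of 0.1, and 1 to 18 with a mouse left out. DESeq2 gave an adjusted p to 2724 of the 9025 genes. An alternative in which a gene had no adjusted p was not counted for that gene. Uqcrb passed in 22 of 23 alternatives on its own scale (adjusted p 1.05e-05 to 0.0595), Rpl22l1 in 20 of 21 (0.000194 to 0.134), Gm15421 in 4 of 22 (0.0369 to 0.247), Cdkn1a in 15 of 23 (0.000704 to 0.132), Arpc2 in 15 of 23 (0.000341 to 0.229), Lingo1 in 13 of 23 (0.00197 to 0.342) and Cdk5r1 in 8 of 21 (0.00794 to 0.228). For features (15) it was 139 with no filter, 129 with DESeq2, 40 with spike-in scaling and 8 to 47 with a mouse left out. For the right side (5) it was 17, 23 and 3 in that order, and 0 to 6. For the left side (0) it was 22 with no filter, 5 with DESeq2, and 0 to 1. For left against right (0) it was 9 with no filter, 18 with DESeq2, and 0 to 3. Of the lists (11), 0 were called with an estimated correlation, 0 by fry, and 7 to 14 with a mouse left out, 7 without WT replicate 1. The spike-in ratio ranged from 0.17 to 0.31 with a mouse left out. The gene body share on the left alone was 0.26. For genes near Esr2, Fisher's exact p was 0.0198 at an unadjusted p under 0.01 and 0.000119 at one under 0.001. The test on genes past the adjusted threshold gave a Fisher's exact p of 0.0706 to 1 with a mouse left out. The unadjusted thresholds were not tested this way. Apart from fewer counts after thinning and a looser threshold at 0.1, the cause was not tested.

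With the replicate number as a block (mice 2 to 6), 11 genes were called per mouse and 1 on the right, Gm15421 (0.124), the synaptic vesicle list (0.0636) and the ion channel list (0.144) were not called, and the glutamatergic list (0.0209) and, as lower, the oxidative phosphorylation list (0.0189) were; the mitochondrial difference was -0.97 and the gene body difference 0.34, both with an exact permutation p of 0.0625, the smallest 5 pairs allow. The numbers do not pair the mice: same-numbered mice correlated by -0.039 to 0.091, and 2 of 5 BERKO mice correlated best with their own number.

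Lists that changed direction, given as camera's adjusted p: under the block, myelin 0.857, deep layers 0.901, striatal 0.82, glycolysis 0.857, interferon 0.901; without the 3 libraries, myelin 0.516, deep layers 0.866, striatal 0.923, interferon 0.923, circadian 0.923; with promoter features alone, deep layers 0.862, ion channels 0.594, oxidative phosphorylation 0.118, steroid receptors 0.782, circadian 0.964; on the left alone, oligodendrocyte precursor 0.344, deep layers 0.85, glycolysis 0.0733, ribosomal 0.344; on the right alone, oxidative phosphorylation 0.875, cholesterol 0.875. With a mouse left out the range was 5.31e-06 to 0.954 (myelin), 0.318 to 0.983 (oligodendrocyte precursor), 0.383 to 0.962 (deep layers), 0.666 to 0.979 (striatal), 0.0403 to 0.942 (oxidative phosphorylation) and 0.253 to 0.954 (interferon). The cause was not tested. At the depth and spread of these mice, a log2 change of 1 was recovered in 40.2% of simulated genes.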

Other observations

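All tests of the side lists were chosen only after the single-gene results were seen; the genes of single libraries were chosen after their values were seen and are given without a test.

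Astrocyte genes were lower in the right than in the left biopsies, a difference that cannot be told apart from plate row, since 0 plate rows held both sides. Of 25 measured members, 22 were lower on the right, with a median of -0.35 log2 units, and the list was called by camera with an estimated correlation (adjusted p = 0.0218) and by fry (adjusted p = 0.0129). Glutamatergic synapse genes had a median of 0.21, with 8 of 30 members lower on the right (adjusted p = 0.0465 with an estimated correlation, 0.0642 by fry). Meningeal fibroblast genes had a median of -0.56, lower in 11 of 11 members, but were not called with an estimated correlation (adjusted p = 0.279). Of the 25 lists tested this way, the other 22 were not called with an estimated correlation either.

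The 3 WT libraries apart on the first principal component had high values of some neuronal genes and low values of others on a log2(CPM + 1) scale. Crym, a thyroid hormone-binding protein of deep cortical layers, was at 9.14 in the right and 8.79 in the left biopsy of WT replicate 1 and at 7.83 in the left biopsy of WT replicate 2. Pnck, a calcium/calmodulin-dependent kinase, was at 9.62, 10.05 and 9.90, and Hap1, the huntingtin-associated protein, at 8.57, 8.12 and 8.81. In the other 19 libraries Crym, Pnck and Hap1 were lower than in each of these 3. As many of the leading genes were low in them: Lamp5, a lysosomal membrane protein of neurons, was at 5.57, 4.56 and 7.28, and Tshz2, a zinc finger gene, at 0, 0 and 3.78, below each of the other 19 libraries.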
